A study of Homo sapiens with 4 samples.

How the data were processed

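The series holds CUT&Tag libraries of MCF-7 cells, a human breast cancer line that depends on oestrogen receptor signalling. CUT&Tag directs a transposase to an antibody target on chromatin, so that the DNA released and sequenced lies around the target. Per the labels, 1 library was made for ZNF408, a zinc finger protein, 1 for H3K4me3, the trimethylated histone mark of active promoters, and 2 for SETD1A, an H3K4 methyltransferase of the COMPASS family. The labels do not say whether the SETD1A replicates came from separate cultures. RNA-seq and ATAC-seq libraries that the series design mentions were not analysed here.

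Per the submitters' processing notes, BWA, MACS2 and bedtools were used with the build GRCh38 (hg38). Versions, parameters, the use of a control library, duplicate removal and filters on problem regions are not given in the sources used here. Each library has its own deposited list of regions, so replicates were called separately. Each row of the deposited files gives a region, a score, a fold enrichment over the background as a ratio, the −log10 of a p-value, the −log10 of a q-value, and the distance of the summit from the region start. The authors' −log10 p reached down to 2.00 in the ZNF408 and H3K4me3 lists, whose region names mention 0.01, and down to 1.30 in both SETD1A lists. The lists were therefore permissive and did not share a threshold. A −log10 q of 2 was reached by 27.9% of ZNF408 regions, 81.5% of H3K4me3 regions and 43.5% and 30.8% of SETD1A regions. A region at a gene can thus be weak. The deposited score followed 10 times the authors' −log10 p and was not used. Fold enrichments are the authors' own values and served only to describe, rank or filter regions within a list.

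Rows on chromosomes 1 to 22 and X were kept, and rows on all other sequences were only counted. No rows of a list overlapped, so that merging changed nothing. Total read counts were not used here. Depth was instead read from the lists: fold and −log10 p together fix the pileup, the whole number of fragments over the summit, and the background it was tested against. Both were recovered for 99.9% to 100% of rows of a library, with the p reproduced within 0.001 on the −log10 scale. The most common background, called the floor below, stands for the mean coverage of the genome by a library. It was 0.976 for ZNF408, 1.12 for H3K4me3, 1.65 for SETD1A replicate 1 and 0.930 for SETD1A replicate 2. The background over the floor at a region describes how much local coverage exceeded that mean, and was summarised over regions within 50 kb of a gene or in bins of 5 Mb with at least 20 regions.

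Genes came from a RefSeq table of the same build, which gave the span of 19974 protein-coding genes but not their strand, exons or sequence. Start and end of transcription could not be told apart. The design had named windows of 1000 bp around transcription start sites; windows of 1000 bp around both ends of each gene span were used in their place, 39948 gene ends in all. Other regions were divided by summit into gene bodies and intergenic. Exons and introns, sequence words at ZNF408 summits and a match of gene lists on CpG content need a genome and were not computed. Of the members of the 30 gene lists, 606 were found in the table and 2 were not.

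A SETD1A region was a merged region with a row from both replicates. Regions were shared when they overlapped by at least 1 bp. Each observed share was divided by the mean share after 1000 circular shifts of the first list within each chromosome. Odds ratios over gene ends carry a 95% interval from 1000 resamples of 5 Mb blocks. Shares carry Wilson 95% intervals, which cover counting error only. For each list, the number of members with a region at either end was placed among 10000 random lists of the same size, matched on the presence of H3K4me3 for ZNF408 and SETD1A and unmatched for H3K4me3. Lists at or above the 97.5th or at or below the 2.5th percentile were called. The ZNF408 or H3K4me3 fold given for a gene is the highest at either end of its span, which need not be the promoter. SETD1A folds of a gene are those of the region with the highest mean of the replicates. With 1 or 2 libraries per target no p-value was computed, and percentiles and intervals describe these libraries only. Genes are not independent replicates. Random lists drew genes singly, while neighbouring members of a list can share a region, as H2AC11 and H2BC11 did for ZNF408. Percentiles of clustered lists may therefore be too extreme. A list with a region at every member cannot rank higher, so a short list may be unable to reach the upper bound. With 30 lists per target, some pass a bound by chance, and no correction was made for this.

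The tests, the gene lists, the rule for named genes and most alternatives were set before the data were examined. That rule names the genes of both targets, every member of the MHC class I list, up to 4 members of every other list with all 3 targets at one end in order of ZNF408 fold, and up to 3 members with H3K4me3 but no ZNF408 region in order of H3K4me3 fold. It also names the 10 genes with the highest ZNF408 fold, the first 5 genes with ZNF408 and H3K4me3 but no SETD1A region, the first 5 with SETD1A but no ZNF408, the 5 strongest ZNF408 regions without another target, and the 5 widest H3K4me3 regions. Alternatives set in advance were a −log10 q of at least 5, equal numbers of top regions, a reciprocal overlap of 50%, summits within 200 bp, each SETD1A replicate alone, the union of replicates, random positions, windows of 500 and 2500 bp, unmatched lists and rows left unmerged. Chosen after seeing the data were a −log10 q of at least 2, moves of regions by 20 to 200 kb, lists matched on H3K4me3 fold, lists at the H3K4me3-marked end, and leaving out the 10 bins of 5 Mb with the highest ZNF408 background. The recovery of pileups and backgrounds was chosen after the lists had been read, while the outcomes of 2 tests built on it, the H3K4me3 background near amplified genes and the ZNF408 background over bins, were predicted before they were seen.

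The overlap ratio, the odds ratio, the upper bound for lists and the recovery of pileups were tested on simulated data, and the other steps were not. Random regions of ZNF408 widths overlapped SETD1A at 1.00 times the shifted share (92652 regions). In 200 simulated sets of 10000 gene ends with true odds ratios of 1 and 4, the median estimates were 1.00 and 4.00, and 95% and 92% of intervals held the true value. Of 400 random lists of 20 genes, 3.75% reached the upper percentile bound. Simulated gene ends and genes were drawn independently, so these checks do not cover regions that cluster along the genome or follow H3K4me3. All of 20000 simulated pileups were recovered. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.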

Results

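CUT&Tag was used to map ZNF408, SETD1A and H3K4me3 in MCF-7 breast cancer cells, in 4 libraries. The ZNF408 list held 92652 regions with a median width of 366 bp, and the H3K4me3 list held 31935 regions of 933 bp. The SETD1A lists held 127851 regions of 513 bp in replicate 1 and 166997 regions of 447 bp in replicate 2. Both SETD1A replicates had a region at 75364 places. The background floor, which stands for mean coverage, was 0.976 for ZNF408, 1.12 for H3K4me3 and 1.65 and 0.930 for the SETD1A replicates. ZNF408 and H3K4me3 have no replicate, and coordinates are of GRCh38. Fold enrichments are the authors' values and are compared only within a list. The series title names ZNF408 loss and immune escape, so gene groups of antigen presentation and immune signalling were among those examined.

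The genes of both proteins carried all 3 targets. At the start of the span of the ZNF408 gene (chromosome 11, 46701031 to 46705912) the fold enrichment was 4.93 for ZNF408, 9.46 and 9.04 for the SETD1A replicates and 6.64 for H3K4me3. At the SETD1A gene (chromosome 16, 30957754 to 30984664) it was 5.03 for ZNF408, 8.81 and 8.25 for SETD1A and, at the other end of the span, 11.2 for H3K4me3. H3K4me3 was the target most concentrated at gene ends, with 40.7% of its regions there. The share was 13.1% for ZNF408, 16.6% and 13.3% for the SETD1A replicates, and 23.4% for SETD1A regions found in both. These shares were 9.34, 4.09, 4.42, 3.73 and 5.52 times those of shifted regions. Of the remaining ZNF408 regions, 37428 had their summit in a gene body and 43104 lay between genes. The lists differed in strength: 67.0% of H3K4me3 regions reached a −log10 q of 5, against 10.2% for ZNF408 and 27.0% and 15.3% for the SETD1A replicates. Among regions of that strength, 49.3% of ZNF408, 56.4% of H3K4me3 and 41.8% and 44.1% of SETD1A regions were at gene ends.

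The SETD1A replicates shared their strong sites. Of the regions of replicate 1, 60.3% overlapped replicate 2 (Wilson interval 60.0% to 60.6%), 7.40 times the shifted share, and 47.4% of replicate 2 regions overlapped replicate 1. In 10 classes of replicate 1 regions by fold, equal in number, 99.2% of the highest class overlapped replicate 2, against 30.1% of the lowest. At gene ends the overlap was 82.7%, and away from them 55.4%. Over the shared regions Spearman's rho of the fold was 0.743, across regions, which are not independent replicates. At AURKA, a mitotic kinase gene, the SETD1A folds of the replicates were 8.84 and 8.60.

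At the genes where ZNF408 was strongest, SETD1A and H3K4me3 were present as well. Neither this nor the overlaps below were set against the accessibility of the DNA, since the ATAC-seq libraries were not analysed. The 10 genes with the highest ZNF408 fold all carried the 3 targets at one end. They included SF1, a splicing factor, with a ZNF408 fold of 15.5, a shared region between TPR, a nuclear pore protein, and ODR4 with 15.3, a shared region between METTL25 and CCDC59 with 15.2, FAM168A with 15.0, TMEM14B with 14.9 and TOMM40, a mitochondrial import channel, with 14.7. The 2 highest were LOC124905351, beside the end of chromosome 3, with 23.8, and FAM86B1, a member of a duplicated gene family, with 17.1. SETD1A folds at SF1 were 10.8 and 13.6, at TPR and ODR4 10.3 and 14.8, and at METTL25 and CCDC59 14.0 and 18.8.

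Over all ZNF408 regions, 26.6% (26.3% to 26.9%) overlapped SETD1A, 6.30 times the shifted share of 4.22%, which spanned 3.81% to 5.57% over the shifts. At gene ends the overlap was 77.4% and away from them 18.0%, the latter 6.16 times the shifted share. In 10 classes of ZNF408 regions by fold, equal in number, it was 76.0% in the highest class, 16.6% in the lowest and least in class 5, at 8.12%. Where the regions overlapped, Spearman's rho of the ZNF408 and SETD1A folds was 0.515 across regions. The ratio was 5.61 against replicate 1 alone and 5.12 against replicate 2 alone. At a −log10 q of at least 5 in all lists it was 32.2, and against regions moved by 20 to 200 kb it was 4.01.

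**Figure D1:**
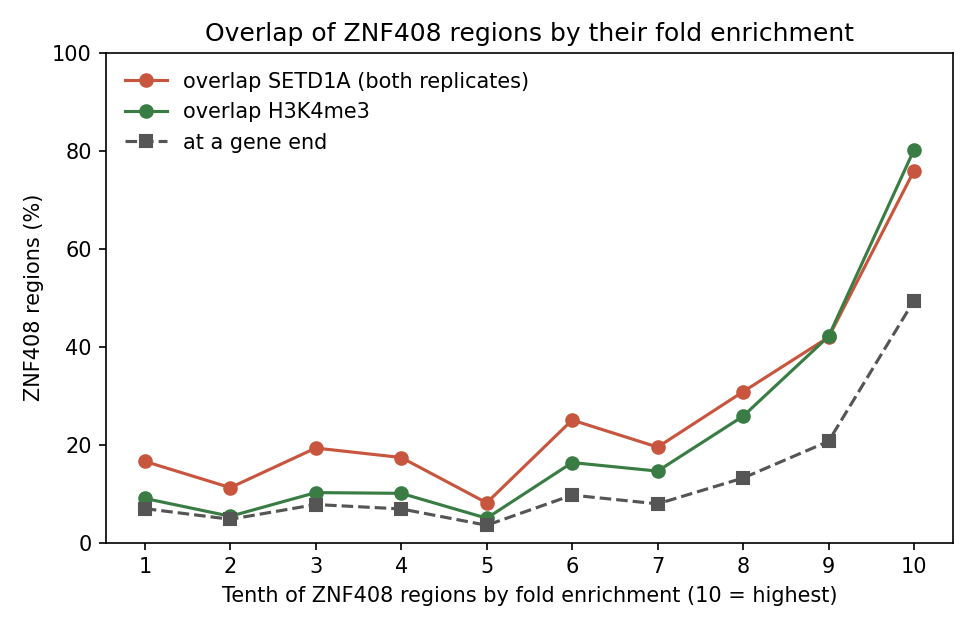
Percent of ZNF408 regions (y axis) that overlapped SETD1A regions of both replicates, overlapped H3K4me3 regions, or lay at a gene end, in 10 classes of ZNF408 regions by fold enrichment, equal in number (x axis, 10 the highest). In the highest class 76.0% overlapped SETD1A, 80.2% overlapped H3K4me3 and 49.4% were at gene ends.

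ZNF408 also lay at H3K4me3. Of its regions 21.9% (21.6% to 22.1%) overlapped H3K4me3, 11.8 times the shifted share, and in the class with the highest ZNF408 fold the overlap was 80.2%. At gene ends 78.8% of ZNF408 regions overlapped H3K4me3, and away from them 12.6%, 15.4 times the shifted share. Over all gene ends, 81.7% of those with ZNF408 had H3K4me3 against 14.5% of those without, an odds ratio of 26.2 (23.9 to 29.0). The odds ratio was 14.3 at gene ends with SETD1A and 8.55 at those without. Among the genes with both, KMT2A, a COMPASS family methyltransferase, had a ZNF408 fold of 14.3 and an H3K4me3 fold of 5.33, and RPS19, a ribosomal protein gene, had 13.5 and 7.42. In 9711 genes longer than 10 kb with H3K4me3 at 1 end alone, ZNF408 was at the marked end of 75.8% and at the opposite end of 9.25%, and SETD1A at 90.6% and 17.8%. The odds ratio over all gene ends was 157 at a −log10 q of at least 5, 39.1 with windows of 500 bp and 14.9 with windows of 2500 bp.

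SETD1A, which methylates H3K4, overlapped H3K4me3 in 31.1% of its regions (30.8% to 31.5%), 11.6 times the shifted share. The share was 76.5% at gene ends and 16.3% away from them. In the highest of 10 classes of SETD1A regions by fold it was 76.7%, against 9.78% in the lowest. From the side of the mark, 64.0% of H3K4me3 regions overlapped SETD1A and 60.0% overlapped ZNF408. The remaining 68.9% of SETD1A regions had no H3K4me3. They had a median width of 825 bp against 1274 bp for those with the mark, and a median fold of 3.07 against 5.21, and 7.97% were at gene ends against 57.5%. Among the genes with SETD1A and no ZNF408, EPHA5, a receptor tyrosine kinase gene, had SETD1A folds of 15.8 and 14.0, TP53TG3 15.5 and 11.5, and TP53TG3F 13.7 and 12.7, with no H3K4me3 region at their ends. The latter genes belong to a duplicated family. ZNF302, a zinc finger gene, had 11.9 and 13.4, with an H3K4me3 fold of 11.4, and HEMK2, a methyltransferase gene, had 12.1 and 12.8, with 13.9. Each replicate alone gave a lower ratio of overlap with H3K4me3, 9.21 for replicate 1 and 7.39 for replicate 2. At a −log10 q of at least 5 the share of SETD1A regions without H3K4me3 was 37.4%.

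Most gene ends with ZNF408 and H3K4me3 also had SETD1A. All 3 targets were present at 10352 gene ends, 25.9% of the total, in 9777 genes. At gene ends with H3K4me3, SETD1A was present at 93.3% of those with ZNF408 and at 73.2% of those without, an odds ratio of 5.11 (4.49 to 5.80). Without H3K4me3 the shares were 34.8% and 14.8%, an odds ratio of 3.06. Within 4 equal classes of gene ends by H3K4me3 fold, from the lowest up, the odds ratio was 4.46, 5.98, 6.12 and 3.90. Fold is taken over a local background, with a median of 3.51 times the floor for H3K4me3. The 5 widest H3K4me3 regions had folds of 3.16 to 3.42, against a median of 5.73. Classes by fold therefore need not hold the amount of the mark fixed. ZNF408 and H3K4me3 without any SETD1A region were seen in 274 genes, led by KAT6B, an acetyltransferase gene, with a ZNF408 fold of 12.5, TLE4, a corepressor gene, with 10.1, the zinc finger genes ZNF461 and ZNF567 with a shared region of 8.63, and ATF7IP2 with 8.37. H3K4me3 was present without ZNF408 in 2822 genes. The count of genes with all 3 targets was 5227 at a −log10 q of at least 5.

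Of the ZNF408 regions, 53755 (58.0%) overlapped no region of the other targets, with either SETD1A replicate counted. They were narrow and weak, with a median width of 330 bp and a median fold of 3.04, and 55.4% of them lay between genes and 2.46% at gene ends. The strongest lay on chromosome 17 at 25389758 to 25390228, with a fold of 21.5, 1904205 bp from the nearest protein-coding gene end. The next lay on chromosome 20 at 28307858 to 28308501, with 20.8, on chromosome 14 at 32484385 to 32485118, with 19.7, where the nearest end was that of AKAP6 at 155782 bp, on chromosome 12 at 130646071 to 130646439, with 16.2, nearest RIMBP2 at 69943 bp, and on chromosome 17 at 25569108 to 25569413, with 16.2. The chromosome 20 region and the other chromosome 17 region lay 2505272 and 1724874 bp from the nearest gene end. Repeated or problem sequence was not filtered out here, so a high fold at such places need not mark binding. The share without the other targets was 18.2% at a −log10 q of at least 5, and 62.4% and 64.7% with a single SETD1A replicate counted.

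Wide H3K4me3 regions carried both proteins more often than narrow ones. The widest were 4790 bp at the end of DUSP4, a phosphatase gene, on chromosome 8, 4677 bp near BCOR, a corepressor gene, on chromosome X, 4657 bp at H2BC21, a histone gene, on chromosome 1, 4594 bp at HNRNPUL2 on chromosome 11 and 4573 bp near TOB2 on chromosome 22. From the narrowest to the widest of 4 equal classes of H3K4me3 regions, the share with ZNF408 was 37.0%, 49.9%, 65.4% and 87.5%, and the share with SETD1A 37.8%, 47.6%, 75.7% and 94.8%. Wide regions are met more often by chance, and relative to shifted regions the ZNF408 share was 12.8, 12.8, 11.4 and 10.4 times as high and the SETD1A share 8.72, 9.47, 11.4 and 10.8 times. Gene ends made up 9.82% of the narrowest class and 81.9% of the widest. With a reciprocal overlap of 50% the ratio of the ZNF408 shares in the widest and narrowest classes was 0.840, against 2.37 by simple overlap.

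Of the 22 MHC class I antigen presentation genes, all carried SETD1A (98.2nd percentile) and 21 carried H3K4me3. SETD1A was also at every member of 3 other immune lists. These were interferon signalling and NF-kB pathway genes (17 of 17, both at the 88.7th percentile) and the class II transcription machinery (7 of 7, 72.9th). A list with every member occupied cannot rank higher, so these lists could not reach the upper bound. The rank of the class I list rests in part on HLA-G, its only member without H3K4me3, with SETD1A folds of 2.45 and 3.82. ZNF408 was at 18 of the class I genes, against 16.8 in matched random lists (72.9th percentile). Some of these regions were weak: the −log10 q was 0.855 at HLA-F and at PDIA3 and 1.62 at HLA-C. Of the genes of classical heavy chains, HLA-A had a ZNF408 fold of 4.36 and HLA-C of 3.42, while HLA-B had none and SETD1A folds of 7.34 and 5.91. B2M, the light chain, had 5.06. The peptide transporter genes TAP1 and TAP2 had 6.77 and 6.58, TAPBPL had 9.15 and PSME2, a proteasome activator gene, had 8.43. The TAP1 value was that of a region shared with PSMB8, and the region shared with PSMB9 at the other TAP1 end had 5.08. At HLA-F, ZNF408 (3.04) lay at the end opposite to the strongest H3K4me3 region. The other members without ZNF408 were HLA-G, ERAP2 and NLRC5, the last a transactivator of class I genes with an H3K4me3 fold of 13.03. The SETD1A percentile for this list was 95.1 without replicate 1 and 95.5 without replicate 2, 95.4 with windows of 2500 bp, 95.9 at a −log10 q of at least 2 and 91.1 with the union of replicates.

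ZNF408 was seen less often than in matched random lists at interferon-stimulated genes, the antiviral genes downstream of interferon, and at chemokines. Of the 30 lists, these 2 were at or below the lower bound for ZNF408 and 7 were at or above the upper. Among 30 lists some pass a bound by chance, so a low rank of a single list is weak evidence. Of 24 interferon-stimulated genes, 10 carried ZNF408 against 14.7 expected (1.25th percentile), while 17 carried H3K4me3 and 19 SETD1A. OAS3 had a ZNF408 fold of 4.94 and USP18 of 4.05. OASL, IFIT2 and OAS1 had none, with H3K4me3 folds of 11.8, 8.65 and 7.64. Of 16 chemokines, 2 carried ZNF408 against 5.34 expected (1.22nd percentile), 4 carried H3K4me3 and 6 SETD1A; CXCL16, CXCL2 and CXCL3 had H3K4me3 folds of 8.55, 7.09 and 3.78 and no ZNF408. The percentile of the interferon-stimulated genes was 4.26 with windows of 500 bp, 3.39 with windows of 2500 bp and 4.33 without matching, all short of the bound. That of the chemokines was 8.60 at a −log10 q of at least 5, 3.37 with equal numbers of regions and 4.32 with windows of 500 bp.

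The other immune lists lay inside the bounds for ZNF408. The class II transcription machinery could not rank higher, since every member carried ZNF408. Genes of nucleic acid sensing carried it at 7 of 15 members against 10.0 expected (3.49th percentile), with RIGI at a fold of 6.69 and TBK1 at 5.78, and none at ADAR, MAVS and STING1. Interferon signalling genes carried it at 16 of 17 (94.0th), with JAK2 at 9.70 and STAT2 at 8.97 and none at IFNGR2, and NF-kB pathway genes at 16 of 17 (94.0th), with NFKBIB at 8.24 and none at TRAF6. Checkpoint ligand genes carried it at 9 of 17 (59.8th), with NECTIN2 at 6.30 and CD47 at 4.45. CD274, which encodes PD-L1, had none, with an H3K4me3 fold of 10.1 and SETD1A folds of 2.90 and 3.75. NK cell ligand genes carried it at 7 of 10 (57.1st), with ULBP1 at 5.27 and MICA at 4.22, MHC class II genes at 5 of 12 (27.7th), with none at CIITA, and the class II transcription machinery at 7 of 7 (90.1st), with NFYA at 10.0. Without matching on H3K4me3, 4 immune lists passed the upper bound for ZNF408: interferon signalling and NF-kB genes, both at 99.935, the class II transcription machinery at 98.7 and MHC class I genes at 98.675. For SETD1A, interferon-stimulated genes, at 84.6, passed it with either replicate alone (97.93 and 98.995) and with the union (99.915), and genes of nucleic acid sensing, at 84.5, at a −log10 q of at least 5 (99.995) and of at least 2 (97.96). Checkpoint ligand genes, at 96.2 for SETD1A, passed it with windows of 500 bp (98.32) and at a −log10 q of at least 2 (97.885).

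ZNF408 was at 38 of 38 cytosolic ribosomal protein genes (30.04 expected), with RPS19 at 13.5 and RPS27A at 11.6, at 26 of 26 core spliceosome genes (20.5 expected), with SRSF1 at 8.67, and at 23 of 24 DNA damage response genes (18.4 expected), with MLH1, a mismatch repair gene, at 11.7, and TP53 at 9.31. Of the COMPASS genes 19 of 20 carried it (15.2 expected), with KMT2A at 14.3 and RBBP5 at 11.1, of the mitochondrial ribosome and respiratory chain genes 29 of 31 (24.5 expected), with UQCRC2 at 13.1 and none at ATP5F1A, and of the replication-dependent histone genes 28 of 30 (23.1 expected), with a region shared by H2AC11 and H2BC11 at 9.95. With the genes amplified in MCF-7, at 20 of 21, these 7 lists reached the upper percentile bound. In 4 of them, the ribosomal, spliceosome, DNA damage and histone lists, this held in every alternative run. The COMPASS list was at 95.6 at a −log10 q of at least 5 and at 88.6 with windows of 2500 bp. The mitochondrial list was at 82.6 at a −log10 q of at least 5, 95.1 with equal numbers of regions, 90.6 with windows of 2500 bp and 96.8 at the marked end. Proteasome genes carried ZNF408 at 28 of 31 (97.3rd) and cell cycle genes at 25 of 27 (96.5th), with AURKA at 11.2 and CDK2 at 10.3. The proteasome list passed the bound in 7 alternatives, at 98.3 to 99.995, and the cell cycle list with windows of 500 bp (98.9), without matching (99.995) and at the marked end (98.07). H3K4 demethylase genes carried it at 6 of 7 (62.5th) and Wnt and retinal vasculature genes at 11 of 14 (61.7th).

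Histone, KRAB zinc finger and Polycomb-type genes carried SETD1A in fewer cases than matched random lists, as did olfactory receptor genes and liver and keratinisation genes. The 9p21 list did so too, but MCF-7 cells are known to lack its genes. Of the 30 replication-dependent histone genes 20 carried SETD1A against 26.8 expected (0.0150th percentile), although 29 carried H3K4me3 and 28 ZNF408. Random lists drew genes singly, so percentiles of clustered genes such as these may be too extreme. KRAB zinc finger genes of chromosome 19 carried SETD1A at 21 of 29 (2.29th percentile) and ZNF408 at 25 (96.7th), with ZNF544 at a ZNF408 fold of 10.7 and neither protein at ZNF99 and ZNF208. Polycomb-type developmental regulators carried SETD1A at 12 of 30 (0.800th) and ZNF408 at 12 (18.8th), with SOX2 at a ZNF408 fold of 6.88 and HOXD13, ATOH1 and HOXA13 with H3K4me3 and no ZNF408. Of the lists that reached the upper bound for SETD1A, DNA damage response genes (24 of 24, 98.4th), ribosomal protein genes (38 of 38, 98.3rd) and COMPASS genes (20 of 20, 97.7th) were short of it with either replicate alone. Without replicate 1 and without replicate 2 their percentiles were 95.6 and 77.6, 96.2 and 95.4, and 94.8 and 94.9 in that order. The histone list stayed at or below 1.71 except without matching, where it was at 35.3. The KRAB list was inside the bounds under several alternatives, such as 50.5 at a −log10 q of at least 5, and the Polycomb list was at 11.7 without replicate 2 and 2.31 without replicate 1. At a −log10 q of at least 5, 6 lists that were inside the bounds for SETD1A passed the upper one: genes of nucleic acid sensing (99.995), proteasome (99.8), spliceosome (99.77), mitochondrial (99.2), interferon signalling (98.47) and cell cycle genes (98.46). With all regions, the spliceosome, mitochondrial, interferon signalling and cell cycle lists had SETD1A at every member and could not rank higher. For ZNF408 the KRAB list passed the upper bound in 5 alternatives, at 98.1 to 99.9. The Polycomb list passed the lower one at a −log10 q of at least 5 (1.89) and without matching (1.68).

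Luminal and oestrogen receptor genes carried H3K4me3 at 24 of 27 members (99.5th percentile), SETD1A at 23 and ZNF408 at 20 (57.7th), with XBP1 at a ZNF408 fold of 6.39 and GREB1, an oestrogen-induced gene, at 6.23. Basal and mesenchymal genes carried H3K4me3 at 13 of 20 (40.4th), SETD1A at 14 and ZNF408 at 9 (8.96th), with ZEB1 at 7.56 and none at EGFR, MYLK and CDH2. T and B cell markers carried H3K4me3 at 4 of 16 (0.0350th), SETD1A at 6 and ZNF408 at 4 (20.4th). Myeloid, endothelial and fibroblast markers carried them at 4, 8 and 6 of 16, with ZNF408 at the 67.1st percentile. Olfactory receptor genes carried H3K4me3 at 0 of 20, SETD1A at 0 (0.150th) and ZNF408 at 1 (6.02nd), and liver and keratinisation genes at 1, 1 (0.450th) and 4 (50.5th) of 19. The SETD1A percentile of the olfactory receptor genes was 10.98 at a −log10 q of at least 5, 11.96 with equal numbers of regions and 3.52 at a −log10 q of at least 2. That of the liver and keratinisation genes was 11.8 and 18.6 at a −log10 q of at least 5 and of at least 2, 7.83 without replicate 1, 6.61 with the union of replicates and 5.57 with windows of 2500 bp. The SETD1A percentile of the luminal genes, 55.8, was 0.250 at a −log10 q of at least 5, 1.19 with equal numbers of regions and 1.26 at a −log10 q of at least 2, and the ZNF408 percentile of the basal genes was 0.685 at a −log10 q of at least 2. Without matching, the ZNF408 percentiles of T and B cell markers, olfactory receptor genes and liver and keratinisation genes were 0.365, 0 and 0.0650.

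**Figure D2:**
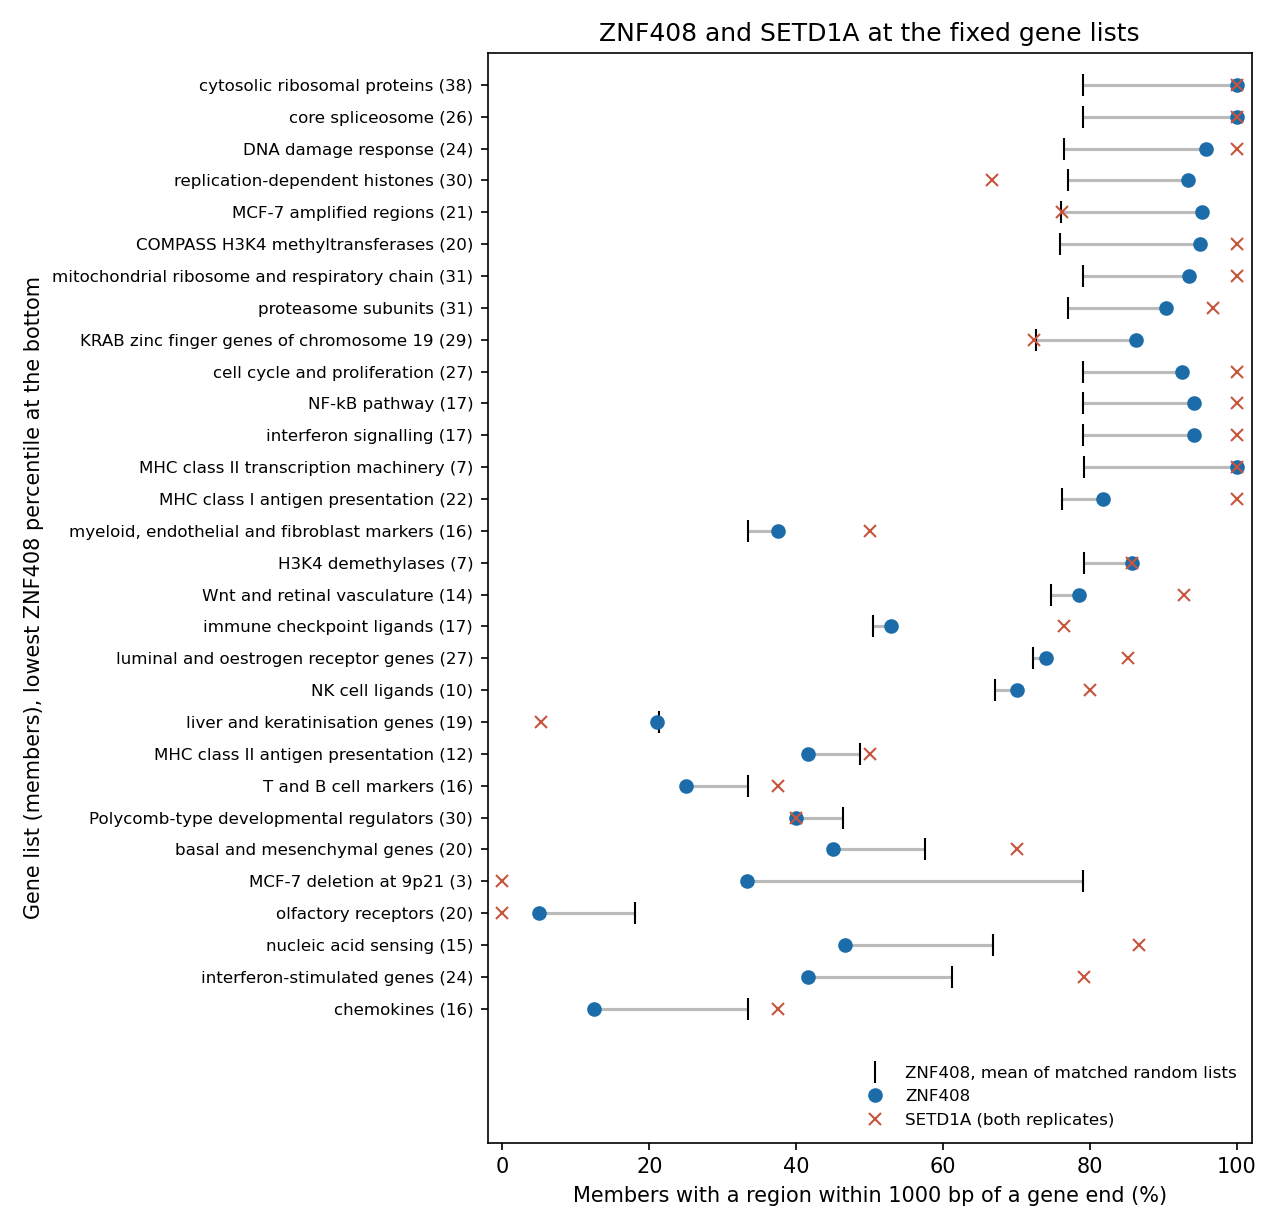
Percent of the members of each fixed gene list with a region within 1000 bp of a gene end (x axis) for ZNF408 and for SETD1A in both replicates, with the ZNF408 mean of 10000 random lists matched on H3K4me3 as black ticks; lists are ordered by ZNF408 percentile. Chemokines (2 of 16) and interferon-stimulated genes (10 of 24) stood lowest, and ribosomal protein genes (38 of 38) highest.

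The libraries differed at the regions of known copy number change in MCF-7. This line carries amplified DNA on chromosomes 17 and 20 and lacks the tumour suppressor gene CDKN2A at 9p21. Within 50 kb of the 21 amplified genes, the median background over the library floor was 11.3 in the ZNF408 library, with 26.2 at TBX2 and 21.8 at ZNF217. It was 4.54 in the H3K4me3 library, and 1.15 and 1.303 in the SETD1A replicates. Single genes were higher in the SETD1A replicates, with 3.94 and 2.99 at ZNF217, 8.75 and 1.20 at TUBD1, and 1.58 and 2.73 at PFDN4. These 4 genes were chosen after their values were seen. Over the medians of all regions of each library these were 9.29, 1.29, 0.929 and 0.944. At BCAS3 and its flanks lay 115 ZNF408 regions and 33 and 52 SETD1A regions. SETD1A was at the ends of 16 of the 21 genes (4.29th percentile, 2.04 at the marked end) and ZNF408 at 20; without the 10 bins with the highest ZNF408 background, which hold most of these genes, the ZNF408 percentile was 84.6. The ratio of overlap between ZNF408 and SETD1A was 6.62 without those bins.

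At 9p21, on chromosome 9, neither SETD1A library had a region between 21 and 23 Mb, where the library densities give 84.4 and 110 by proportion. The stretch without a SETD1A region was 4362 kb long in replicate 1 and 4944 kb in replicate 2. The ZNF408 library had 16 regions between 21 and 23 Mb, against 61.2 by proportion, with 1 of the 3 listed genes, MTAP, named after its values were seen, carrying one (6.27th percentile). H3K4me3 had 8, against 21.1 by proportion, with folds of 12.6 at CDKN2B, 5.22 at CDKN2A and 6.31 at MTAP. The 3 H3K4me3 regions at these genes reached a −log10 q of 5.

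**Figure D3:**
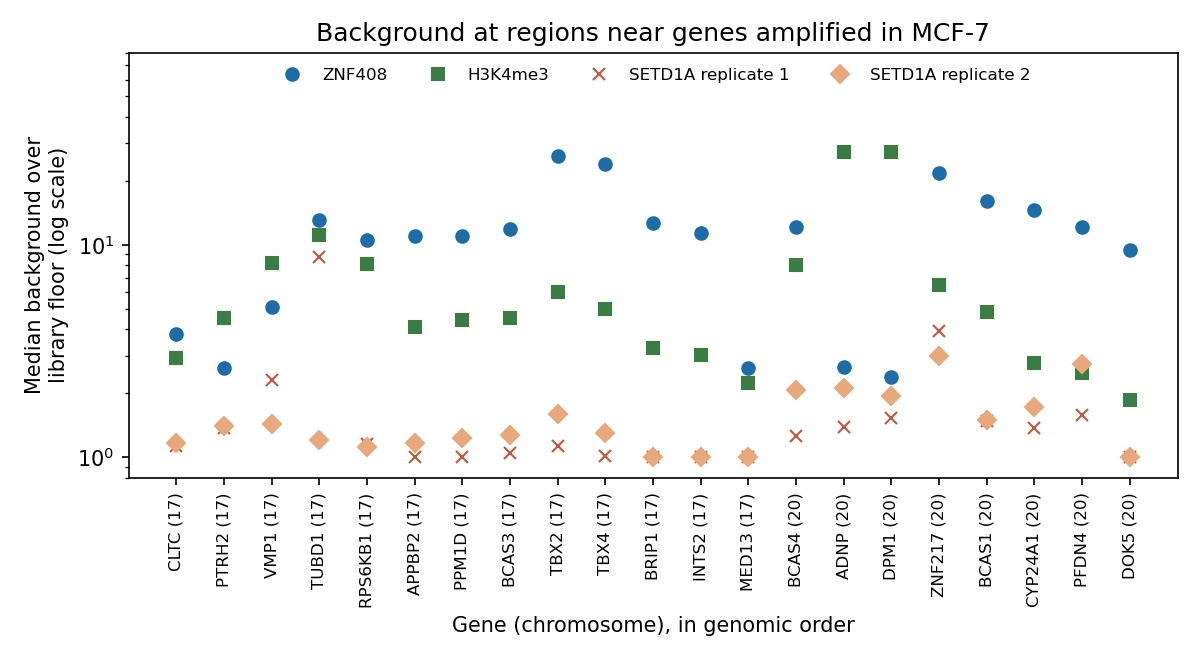
Median background over the library floor (y axis, log scale) at regions within 50 kb of each of 21 genes amplified in MCF-7 (x axis, chromosome in brackets, genomic order), 1 point per library. ZNF408 had a median over genes of 11.3, and SETD1A replicates 1 and 2 had medians of 1.15 and 1.303.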

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

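No tests, chosen before or after the data were seen, were run on these values. Regions on Y, mitochondrial and unplaced sequences, counted together and not analysed further, numbered 770 in the ZNF408 list, 227 in the H3K4me3 list, 513 in SETD1A replicate 1 and 538 in SETD1A replicate 2. They stand out only as signal in data that no comparison used.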

How the results depend on the processing

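A −log10 q of at least 2, moves of 20 to 200 kb, matching on H3K4me3 fold, counts at the marked end and leaving out 10 bins were tests chosen only after the data were seen. Of 980 alternative values, 759 stayed within the spread or on their side of the bound, 97 moved beyond it, 57 no longer passed the bound, 66 newly passed it and 1 reversed. All 53 alternative overlap ratios and odds ratios stayed above 1, but 42 of them moved beyond the spread and 11 stayed within it. All 12 alternative shares of regions at gene ends moved beyond it. Of the alternative list percentiles, over all 30 lists, 232 of 270 for ZNF408, 284 of 360 for SETD1A and 171 of 180 for H3K4me3 stayed on their side of the bound; 25, 38 and 3 newly passed it and 13, 38 and 6 no longer did. The setting with equal numbers of top regions left the H3K4me3 list, the smallest, whole. Its 30 list percentiles under that setting could not move, and they are among the 171. Matching on CpG content and all alternatives for sequence words were not run, since they need a genome. No paired analysis was possible because ZNF408 and H3K4me3 have 1 library each. Median pileups were 6 for ZNF408, 35 for H3K4me3 and 8 and 6 for the SETD1A replicates, and what depth limits was not tested.

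Overlaps are ratios over shifted shares, and width ratios divide the share in the widest class of H3K4me3 regions by that in the narrowest of 4. At a −log10 q of at least 5, values were ZNF408 regions 9452, SETD1A replicate 1 regions 34486, SETD1A replicate 2 regions 25549, SETD1A replicate overlap 30.4, ZNF408 overlap with SETD1A 32.2, ZNF408 overlap with H3K4me3 38, SETD1A overlap with H3K4me3 26.6, the odds ratio for SETD1A 6.47, genes with all 3 targets 5227, the odds ratio for H3K4me3 157, high SETD1A lists 10, ZNF408 regions alone 18.2%, SETD1A without H3K4me3 37.4%, the ZNF408 width ratio 3.55, the SETD1A width ratio 3.23. At a −log10 q of at least 2, values were ZNF408 regions 25850, SETD1A replicate 1 regions 55588, SETD1A replicate 2 regions 51386, SETD1A replicate overlap 18.7, ZNF408 overlap with SETD1A 16.8, ZNF408 overlap with H3K4me3 26.4, SETD1A overlap with H3K4me3 19.5, the odds ratio for SETD1A 5.92, the odds ratio for H3K4me3 76.8, high SETD1A lists 8, ZNF408 regions alone 37.4%, SETD1A without H3K4me3 50.5%, the ZNF408 width ratio 2.71, the SETD1A width ratio 2.86. With equal numbers of top regions, values were SETD1A replicate overlap 29.2, ZNF408 overlap with SETD1A 18.2, ZNF408 overlap with H3K4me3 22.7, SETD1A overlap with H3K4me3 21.7, the odds ratio for SETD1A 6.38, the odds ratio for H3K4me3 61.2, low ZNF408 lists 1, high SETD1A lists 9, ZNF408 regions alone 45.9%, SETD1A without H3K4me3 33.2%, the ZNF408 width ratio 3.2, the SETD1A width ratio 5.99. With a reciprocal overlap of 50%, values were SETD1A replicate overlap 21.8, ZNF408 overlap with SETD1A 14.9, ZNF408 overlap with H3K4me3 36.8, SETD1A overlap with H3K4me3 26.3, ZNF408 regions alone 81.4%, SETD1A without H3K4me3 83.9%, the ZNF408 width ratio 0.84, the SETD1A width ratio 8.64. With summits within 200 bp, values were SETD1A replicate overlap 15.4, ZNF408 overlap with SETD1A 11, ZNF408 overlap with H3K4me3 24.3, SETD1A overlap with H3K4me3 26.5. Against regions moved by 20 to 200 kb, values were SETD1A replicate overlap 3.73, ZNF408 overlap with SETD1A 4.01, ZNF408 overlap with H3K4me3 7.18, SETD1A overlap with H3K4me3 5.91. Without the 10 bins with the highest ZNF408 background, values were SETD1A replicate overlap 7.73, ZNF408 overlap with H3K4me3 12.5, the ZNF408 width ratio 2.47, the SETD1A width ratio 2.48. With the union of SETD1A replicates, values were ZNF408 overlap with SETD1A 4.45, SETD1A overlap with H3K4me3 6.04, high SETD1A lists 1. With windows of 500 bp, values were the odds ratio for SETD1A 5.88, the odds ratio for H3K4me3 39.1, low ZNF408 lists 0. With windows of 2500 bp, values were the odds ratio for SETD1A 4.31, the odds ratio for H3K4me3 14.9, low ZNF408 lists 1, high SETD1A lists 0. With unmatched random lists, values were high ZNF408 lists 14, low ZNF408 lists 5, high SETD1A lists 10. With a single SETD1A replicate the values ranged as follows: ZNF408 overlap with SETD1A 5.12 to 5.61, SETD1A overlap with H3K4me3 7.39 to 9.21, high SETD1A lists 1, ZNF408 regions alone 62.4% to 64.7%, SETD1A without H3K4me3 79.3% to 84.5%, the SETD1A width ratio 2.18 to 2.19. The ZNF408 width ratio reversed under reciprocal overlap by construction, since a narrow region cannot cover 50% of a wide one; for the other values the cause was not tested.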

Other observations

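Chosen only after the results were seen were the tests of gene lists by SETD1A without H3K4me3 and the reverse, the tests of the peak threshold, and all tests of the SETD1A background. The genes named here were also chosen after their values were seen. SETD1A was present without H3K4me3 in 1605 genes. Among random lists matched on H3K4me3, 0 of 30 lists were above the upper percentile bound for these genes and 2 were below the lower, olfactory receptor genes with 0 against 4.93 and liver and keratinisation genes with 1 against 4.45. Immune checkpoint ligand genes held 4, VSIR, LGALS9, CD80 and PDCD1LG2, against 1.99 (92.7th percentile), and myeloid, endothelial and fibroblast markers held 4, ITGAM, CD68, CSF1R and PDGFRB, against 2.96 (75.6th percentile). Without matching both were above the bound, at 97.54 and 98.03. H3K4me3 was at 9 of 17 and 4 of 16 of their members. Interferon-stimulated genes also held 4, against 1.73 (96.1st percentile, and 92.2nd without matching), inside the bounds.

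H3K4me3 was present without SETD1A in 1141 genes. These included 9 replication-dependent histone genes, such as H4C4, H3C4 and H1-5, 6 Polycomb-type developmental regulators, such as LHX2 and HOXA10, 5 KRAB zinc finger genes of chromosome 19, the amplified genes TBX2, ADNP, BCAS1 and DOK5, and all 3 genes of the 9p21 list. The counts are no result apart from the SETD1A counts of these lists, from which they largely follow. Matched on H3K4me3, the KRAB and amplified lists were inside the bounds, at 96.0 and 94.8, and were above without matching. In bins of 1 Mb, 35 bins with at least 5 ZNF408 regions had none in either SETD1A replicate, and 12 bins with at least 5 regions in each SETD1A replicate had no ZNF408 region.

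On the median over the amplified genes, the SETD1A libraries lacked the raised background of the ZNF408 library, at 1.15 and 1.303 times the floor against 11.3, although single genes were higher, such as ZNF217 with 3.94 and 2.99, TUBD1 with 8.75 and 1.20 and PFDN4 with 1.58 and 2.73. Lower depth is argued against for replicate 1, whose floor was 1.69 times that of ZNF408. For replicate 2, at 0.953 times, the value fell between the bounds set for the test. Its floor of 0.930 was close to the 0.976 of ZNF408, and replicate 1, with a higher floor, showed the same lack. The test as set therefore decides nothing for replicate 2, though its floor gave no sign of much lower depth. The floor stands in for depth, and the use of a control library, which could shift it, is not known. Cells without the MCF-7 amplifications in the SETD1A libraries could account for it, and this cannot be told apart from other differences between the libraries. In the 10 bins with the highest ZNF408 background the higher SETD1A ratio over all bins was 1.44. However, these bins held 3.65% and 3.33% of SETD1A regions against 5.27% of ZNF408 regions, and some lie at gene-dense chromosome ends. At 60 to 65 Mb of chromosome 17 the background was 9.29 for ZNF408 and 1.23 and 1.44 for the SETD1A replicates. At 60 to 65 Mb of chromosome 3 it was 5.25 against 1.00 and 1.00, but at 60 to 65 Mb of chromosome 20 it was 2.64 against 1.84 and 2.48. The target itself, and a control library that differed between them, stay open, untested. The libraries also differed at 9p21, the other known copy number change of MCF-7. Between 21 and 23 Mb of chromosome 9 both SETD1A libraries had 0 regions, against 84.4 and 110 by library density. ZNF408 had 16 regions there and H3K4me3 had 8. Why the SETD1A lists were empty there was not tested.

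H3K4me3 regions were present at the 9p21 genes, which MCF-7 cells are known to lack. A permissive peak threshold is argued against, since 3 regions kept a −log10 q of at least 5. Cells without the MCF-7 genome in the H3K4me3 library may contribute, and this cannot be told apart from MCF-7 cells that had kept these genes. Background near amplified genes was 1.29 times the library median. The bound set for it was wrong, because the SETD1A libraries compared with it showed no excess, at 0.929 and 0.944. H3K4me3 background was 2.66 at 60 to 65 Mb of chromosome 17, and 2.66 and 2.21 at 45 to 50 and 50 to 55 Mb of chromosome 20. Its median was 1.89 over the 10 bins with the highest ZNF408 background and 1.26 over all bins. The same cells as the ZNF408 library cannot be told apart from other cells. Spearman's rho of weak region density was 0.706 with ZNF408 and 0.761 with each SETD1A replicate. The differences were -0.0546 (-0.0999 to -0.00489) from replicate 1 and -0.0551 (-0.104 to -0.00662) from replicate 2. Rho with ZNF408 was thus the lower. However, the SETD1A lists are larger, and whether size moves rho was not tested, so the bound set for it decides nothing. At the 9p21 genes SETD1A had 0 regions and ZNF408 had 2, both at MTAP. CDKN2A and CDKN2B, where H3K4me3 had regions, had no ZNF408 region. No biological explanation was tested.

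ZNF408 regions without the other targets may come in part from a permissive peak threshold, since their share was 18.2% at a −log10 q of at least 5. The amount of DNA in the ZNF408 library is another candidate explanation, since Spearman's rho between their density and the ZNF408 background over bins of 5 Mb was 0.674, although both come from the same reads. Regional copy number of the cells cannot be told apart from its absence, since rho with the density of regions with SETD1A alone was 0.299 (0.228 to 0.366). Binding by ZNF408 without SETD1A stays open, untested.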
